A study of Mus musculus with 17 samples.

How the data were processed

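RNA was compared in cells of whole limb buds of mouse embryos of embryonic day 11.5. Per the labels' protocols, the cells were cultured for 4 h in medium with 10% serum before purified Wnt3a protein (200 ng/ml) or vehicle was added for 2 or 4 h. Per the labels, polyA RNA (2 ug) from the cells was labelled with Cy5 and hybridised to a spotted cDNA array together with a Cy3-labelled reference. The reference, per the labels, held polyA RNA of total brain and of whole embryos of embryonic day 12.5 in parts of 3 to 1. The sample was in Cy5 on all 17 arrays, so no dye swap was made, and a dye effect cancels in a comparison of groups. The labels state 4 biological replicates per condition, while 5 arrays are given for vehicle at 2 h; all 17 arrays were used.

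Per the file headers, each scanner table holds the median and mean intensity and the median local background of each spot in both channels. The deposited log2 ratio is the red over green ratio of background-subtracted medians with 1 scaling constant per array, per the file headers and a check against the intensity columns. That constant lay between -0.16 and 0.60 on the log2 scale, and the deposited matrix held the same log2 values as the scanner tables. Per the file headers, the tables also give the percent of saturated pixels of each spot and channel, and a score column of spot flags and a score column named failed, whose codes are not explained in the files. Nonzero spot flags occurred on the 2 h arrays only, where they covered 21.5 to 27.6% of spots. The scanner and its software were not stated.

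Each table had 42624 spots. The 693 spots without a reporter name were left out, and the others belonged to 40592 clones. Of these, 23263 carried 1 gene symbol, 181 several and 17148 none. An Entrez gene number present in the reference list of genes was found for 23103 of those with 1 symbol. Axin2, Sox9, Hoxd13 and Hand2 were not matched to a clone and are not analysed here.

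Analysis used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and figures used Python 3.11.15 with matplotlib 3.10.9. Median intensities were corrected for background by the normexp method of limma with an offset of 50, and log2(Cy5/Cy3) was normalised by global loess within each array with a span of 0.3. Spots with a nonzero flag were set to missing and spots of 1 clone were averaged. A clone was tested if its Cy5 signal was at least 1.5 times background on at least 4 arrays and at least 3 unmarked arrays per group gave a value. This left 27243 clones, of which 17488 had 1 symbol, for 9057 genes, and 4623 genes had more than 1 tested clone. The other 13349 clones were left out.

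The 4 groups were vehicle at 2 h (5 arrays), Wnt3a at 2 h (4), vehicle at 4 h (4) and Wnt3a at 4 h (4). A single limma model of the group means was fitted to the 17 arrays, with 13 residual degrees of freedom, 4.08 prior degrees of freedom and a prior SD of 0.21. Contrasts were Wnt3a against vehicle at 2 h and at 4 h, the difference between these effects, and vehicle at 4 h against vehicle at 2 h. Each clone was tested with limma's two-sided moderated test, and p-values were adjusted by Benjamini-Hochberg over all clones of a comparison. A clone was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are limma's moderated ones. The median residual SD over clones was 0.23 on the log2 scale. For arrays, their number limits the precision.

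For lists of genes, 1 clone per gene was taken, that of the highest mean signal, which gave 9057 genes. The list tests need a value on every array, so they used the 8412 genes that had one, and of the 478 places of measured genes on the lists 438 entered the tests. Counts, medians and means of a list are over all its measured genes. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, with camera at an estimated correlation and fry beside it. The lists were Wnt feedback and target genes, Wnt pathway components, FGF/ERK response, BMP/TGF-beta response, hedgehog response, Notch response, chondrogenic, osteogenic, soft connective tissue and limb patterning genes. Further lists were G1/S, G2/M, Myc target and ribosome biogenesis, immediate early, heat shock and unfolded protein, hypoxia and glycolysis, p53 and apoptosis, cholesterol synthesis, inflammatory and interferon, and actin cytoskeleton genes. Lists of cell types covered muscle precursors, ectoderm, endothelium, erythroid cells, macrophages and leukocytes, neural crest and Schwann cells, and neurons. Some genes stand on more than 1 list, such as Msx2 on those of Wnt targets and limb patterning.

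The groups, the model, the 27 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Axin2, Lef1, Mycn, Ccnd1, Sox9 and Col2a1 wherever measured. It further named the 10 highest and the 10 lowest called genes of each Wnt3a comparison, and the 5 highest and 5 lowest of the other comparisons. Such a gene needed every array of 1 group beyond the mean of the other. Of each list it named up to 4 called members, or up to 2 uncalled members as values only. Clones without a gene symbol, or with a RIKEN, EST or predicted name, were counted and not named, and 2 genes that the rule gave at 4 h are counted but not described here.

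The probe amounts in the labels were read as labelling batches; the labels do not say what the amounts mark. Replicate 1 of both 2 h groups had 27 pmol Cy3, the other 2 h arrays 40 pmol, 4 h replicates 1 and 2 had 25 pmol and 4 h replicates 3 and 4 had 30 pmol. Each Wnt3a comparison was repeated with this batch as a block and within each batch. The vehicle comparison shares no batch between its groups, so only a random block could be fitted there. Replicate numbers are shared between the groups of a time, and the labels do not say what a number stands for. At 2 h, deviations from the group means over clones correlated between arrays of the same number at 0.829, 0.333, 0.23 and 0.305 for numbers 1 to 4. Each of these exceeded 0.1, the level set before the data were examined, so the number was taken to pair the 2 h arrays, and the fit with the replicate number as a block is given beside 2 h results that it changes. Only replicate 1 at 2 h correlated best with its own number, but its arrays are the whole 27 pmol batch, so that correlation does not tell a pair from a batch. For numbers 2 to 4 the highest correlation with another number was larger (0.365, 0.368 and 0.411). The level of 0.1 therefore does not tell a pair from a labelling batch, which numbers 2 to 4 share.

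The alternatives covered background correction (none, or plain subtraction), within-array normalization (median centring, print-tip loess), scale normalization between arrays, the filter (none, or 2.5 times background) and the deposited log2 values. They further covered an intensity trend with a robust prior, array weights, the groups of a comparison alone, blocks, a threshold of 0.1, the mean over clones of a gene, other list tests, and leaving out each array. The mean foreground signal, a looser use of spot flags, leaving out clones marked as failed, the random batch block for Wnt3a comparisons, the batch block in the list test, a list test with every measured member (cameraPR on limma's moderated statistics) and the model without both 27 pmol arrays were chosen after seeing the data.

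The procedure was tested on simulated data with the 27243 clones. The simulated noise was independent between clones and arrays and held no labelling batch, so it does not measure false calls in the real data. For the 2 h comparison, 27 of 100 clones changed by 0.5 log2 and 76 of 100 changed by 1 log2 were called, with 2 false calls. For the 4 h comparison these were 24 of 100 and 80 of 100, with 7 false calls. A list shifted by 0.2 log2 in the simulated 4 h comparison had an adjusted p of 2.91e-12.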

Results

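Gene expression was measured on 17 dual-colour cDNA arrays in limb bud cells of mouse embryos of embryonic day 11.5, after 2 or 4 h with purified Wnt3a, a secreted ligand of the beta-catenin pathway, or with vehicle. The groups were vehicle at 2 h (5 arrays), Wnt3a at 2 h (4), vehicle at 4 h (4) and Wnt3a at 4 h (4), and each value is a log2 ratio of the sample to a common reference of brain and embryo RNA. Median sample signal was 2.11 to 3.29 times background on the 2 h arrays and 1.41 to 1.91 times on the 4 h arrays. At least 1.5 times background was reached by 60.9 to 69.6% of spots at 2 h and 47.7 to 56.4% at 4 h. Among vehicle samples, actin cytoskeleton genes lay above the reference (18 of 19, median log2 ratio 1.34), and neuron genes lay below it (0 of 10 above, median -2.83). Erythroid genes also lay below the reference (1 of 11 above, median -2.50).

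The 2 h comparison asked which genes of limb bud cells answer Wnt3a early. Wnt3a raised Apcdd1, a membrane glycoprotein that inhibits Wnt signalling, 1.95-fold (log2 fold change 0.96, SE 0.13, adjusted p = 0.00898, 4 against 5 arrays). The homeobox genes Msx2 and Dlx5, transcription factors of limb and skeletal development, rose 2.37-fold and 1.93-fold (log2 1.24, SE 0.21, adjusted p = 0.0429; log2 0.95, SE 0.16, adjusted p = 0.0387). Both tested clones of Msx2 were called. Ets2, a transcription factor of the ETS family, rose 1.86-fold (log2 0.90, SE 0.14, adjusted p = 0.0264) on 1 of its 5 clones, and Dhrs3, a retinal reductase, rose 1.58-fold (log2 0.66, SE 0.12, adjusted p = 0.0496) on 1 of its 4 clones. Among globins, Hbb-y, an embryonic beta-like globin, rose 2.45-fold (log2 1.29, SE 0.21, adjusted p = 0.0316) and Hba-a1, an alpha globin, 2.20-fold (log2 1.13, SE 0.16, adjusted p = 0.00933). Hbb-y was called on 2 of 7 clones, of which 6 were higher, and Hba-a1 on 1 of 19 clones, all higher. For all these genes every Wnt3a array at 2 h lay above every vehicle array.

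Several genes of interest were not called at 2 h. Lef1, a DNA-binding partner of beta-catenin, had a log2 fold change of 0.63 (SE 0.15, adjusted p = 0.306), and the bright clone of Mycn 0.28 (SE 0.20, adjusted p = 1). A dimmer clone listed as Mycn had 1.44 (adjusted p = 0.132), and an unnamed clone that the file describes as N-myc was called at 1.94 (adjusted p = 1.09e-06); these clones were chosen after their values were seen. Ccnd1, cyclin D1, had 0.04 (SE 0.14) on its brightest clone and up to 0.47 on the others. Col2a1, cartilage collagen II, had -0.14 (SE 0.47). The sign of the Ccnd1 value turned without Wnt3a 2 h replicate 3 (-0.03), and that of Col2a1 without vehicle 2 h replicate 4 (0.02) or Wnt3a 2 h replicate 1 (0.45). Scaling the arrays to equal spread turned the sign of Ccnd1 (-0.17), as did plain background subtraction (-0.01) and the deposited log2 values (-0.05).

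In limma, 15 of 27243 clones were called at 2 h, 15 higher and 0 lower, and 1193 had an unadjusted p under 0.05. The called clones came to 7 named genes and 6 unnamed clones. With the labelling batch as a block 44 clones were higher and 3 lower, and all 15 were among them. A fit of the 2 h arrays of 40 pmol by themselves, with no other group in the model, called 22 clones (21 higher, 1 lower), 9 of which were among the 15, while the 27 pmol batch held 1 array of each group, too few for a count. All 15 had the same direction in both batches, which follows from their Wnt3a and vehicle arrays not overlapping and is no separate support. With the replicate number as a block 24 clones were called (21 higher, 3 lower); Hbb-y H3118A04 (adjusted p = 0.21), Hba-a1 H3122H12 (0.0846) and Dlx5 (0.101) were no longer among them, and Hbb-y H3118A06 was (0.0295).

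Apcdd1 was called at 2 h without any single array, and lost its call only when the arrays were scaled to equal spread, a setting with 0 calls at 2 h (adjusted p over its alternatives 0.000685 to 1). Hba-a1 lost its call without Wnt3a replicate 3 (adjusted p = 0.0764). Msx2 lost it without any of vehicle replicates 1 to 4 or Wnt3a replicates 1 to 4 (up to 0.199), Dlx5 without any of vehicle replicates 2 to 5 or Wnt3a replicates 1 to 4 (up to 0.159), and Dhrs3 without any vehicle replicate or Wnt3a replicates 2, 3 or 4 (up to 0.252). Ets2 lost it without vehicle replicates 3 or 4 or Wnt3a replicates 2, 3 or 4 (up to 0.159), and Hbb-y without vehicle replicates 2, 3 or 4 or Wnt3a replicates 1, 3 or 4 (up to 0.159). An intensity trend with a robust prior ended the calls of Dlx5, Ets2, Dhrs3, Msx2, Hbb-y and Hba-a1. The count was 23 without vehicle replicate 1, 5 without vehicle replicate 3 and 7 without vehicle replicate 4. It was 9, 8, 4 and 5 without Wnt3a replicates 1, 2, 3 and 4 in turn.

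**Figure D1:**
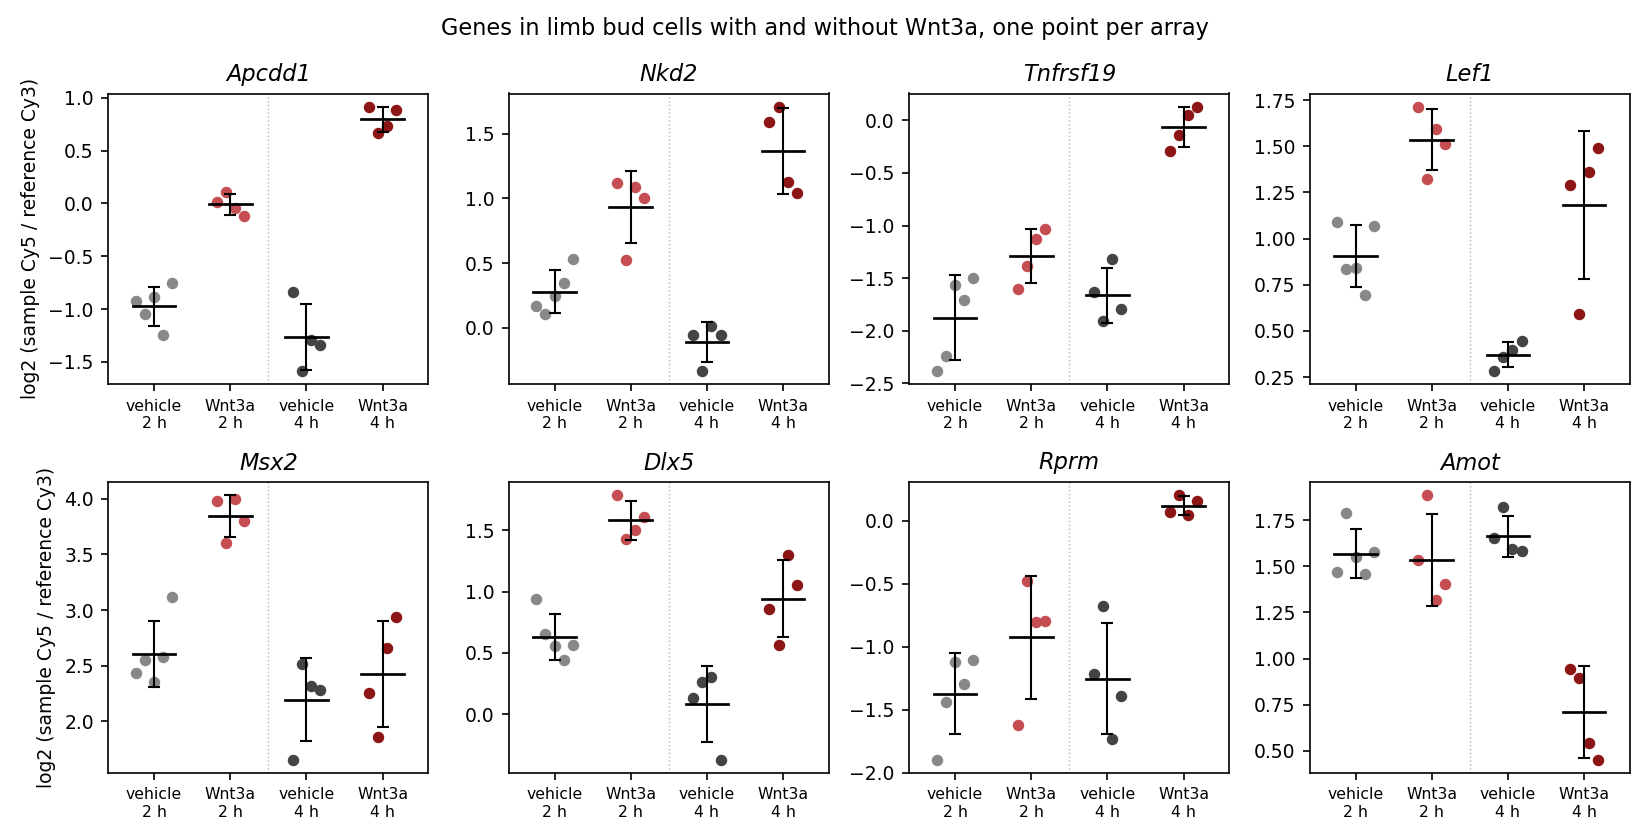
Log2 ratio of sample to reference (y axis) of Apcdd1, Nkd2, Tnfrsf19, Lef1, Msx2, Dlx5, Rprm and Amot in the 4 groups (x axis), with 1 point per array, a line at the mean and a bar of 1 SD. Apcdd1 was 1.95-fold higher with Wnt3a than with vehicle at 2 h and 4.18-fold higher at 4 h, while Amot was called lower at 4 h.

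Wnt feedback and target genes rose as a list at 2 h: 18 of 19 measured members were positive, with a median log2 fold change of 0.28 (camera adjusted p = 5.14e-16; 2.84e-05 with an estimated correlation). Over all genes 2 members were called (Apcdd1, Msx2) and 9 when adjusted over the list alone. The latter included Nkd2, a Dishevelled-binding Wnt antagonist (log2 0.65), Znrf3 (0.67), Lef1 (0.63), Tcf7 (0.38), Tnfrsf19 (0.59), Wif1 (0.47) and Ephb3 (0.28). With the labelling batch as a block Znrf3 was called over all genes too (limma adjusted p = 0.0386). Limb patterning genes also rose (21 of 26 positive, median 0.23, adjusted p = 1.44e-07; 0.00131 with an estimated correlation), with 1 member called over all genes (Msx2) and 2 when adjusted over the list alone (Msx2 and Tbx18, log2 0.70). Osteogenic genes rose (5 of 6 positive, median 0.08, adjusted p = 0.00133; 0.0375 with an estimated correlation), with Dlx5 called over all genes, and Dlx5 and Twist1 (log2 1.07, adjusted p over all genes 0.193) adjusted over the list alone. Twist1 was called over all genes with the labelling batch as a block (limma adjusted p = 0.00429). The other members changed little: Alpl had -0.174, Mmp13 0.075, Spp1 0.085 and Sparc 0.057. FGF/ERK response genes rose (7 of 9 positive, median 0.16, adjusted p = 0.0091). The FGF/ERK call was lost at adjusted p = 0.0985 with an estimated correlation; none of its members was called over all genes and 1, Fgf10 (log2 0.53, SE 0.16), when adjusted over the list alone. Fgfrl1 of that list had 0.41 (SE 0.16). Myc target and ribosome biogenesis genes rose (30 of 40 positive, median 0.11, adjusted p = 0.00236), a call lost at adjusted p = 0.13 with an estimated correlation. That call was also lost without vehicle 2 h replicate 1 (0.114) or Wnt3a 2 h replicate 3 (0.0881); no member was called over all genes or when adjusted over the list alone, and Polr1b (0.36) and Ddx18 (0.32) had the smallest p.

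Erythroid genes, markers of red blood cells, rose at 2 h together with the Wnt and limb patterning genes (8 of 11 positive, median 0.13, adjusted p = 0.000272; 0.0375 with an estimated correlation). On the clones used for the list no gene was called over all genes, and 4 were when adjusted over the list alone: Hba-a1 (1.10), Hbb-y (1.23), Hbb-bh1 (0.63) and Hba-x (0.87). Over all their clones, the mean log2 fold change was 0.83 for Hba-a1 (SD 0.28 over 19 clones), 0.78 for Hbb-y (SD 0.57 over 7), 0.26 for Hbb-bh1 (SD 0.26 over 4) and 0.87 for the single clone of Hba-x. Hbb-b1, an adult-type beta globin, had 0.02 (SD 0.38 over 10 clones). At 4 h the same means were 0.05, -0.11, 0.06, 0.02 and 0.05. Within the 40 pmol arrays the median over the 31 clones of Hba-a1, Hba-x, Hbb-y and Hbb-bh1 was 0.73 at 2 h, and in the 27 pmol pair 1.17. In total 6 lists passed at 2 h, all upward, 4 with an estimated correlation, 4 with fry and 7 with the labelling batch as a block, where soft connective tissue genes joined them (adjusted p = 0.00828). With the replicate block 8 lists passed: soft connective tissue genes were called higher (median 0.08, adjusted p = 0.0311) and neural crest and Schwann cell genes lower (median -0.23, adjusted p = 0.0461) in addition. With every measured member in the test 7 passed, as inflammatory and interferon genes were called higher too (median 0.12, adjusted p = 0.00383; 0.0779 with 13 of their 18 members).

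**Figure D2:**
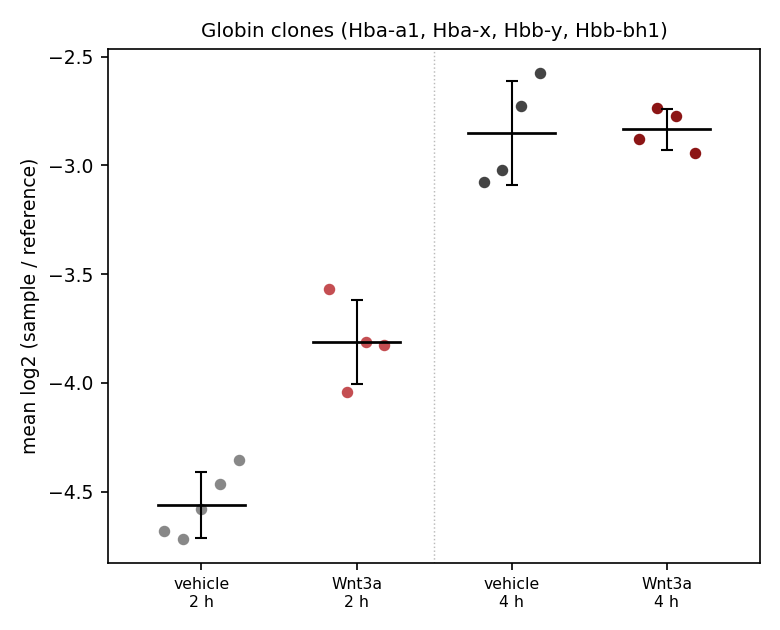
Mean log2 ratio of sample to reference (y axis) over the clones of Hba-a1, Hba-x, Hbb-y and Hbb-bh1 on each array (points) of the 4 groups (x axis), with group mean and SD. Wnt3a arrays at 2 h lay between -4.04 and -3.57, above the vehicle arrays at 2 h (-4.72 to -4.36), and the 4 h groups overlapped.

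The 4 h comparison asked which genes answer Wnt3a after longer treatment. Wnt3a raised the Wnt feedback and target genes Apcdd1 4.18-fold (log2 fold change 2.06, SE 0.14, adjusted p = 1.04e-06, 4 against 4 arrays), Tnfrsf19, a TNF receptor family member, 3.03-fold (log2 1.6, SE 0.20, adjusted p = 0.000893) and Nkd2 2.78-fold (log2 1.48, SE 0.16, adjusted p = 0.000498). Both clones of Tnfrsf19 and both of Nkd2 were called. Rprm, a gene of cell-cycle arrest, rose 2.59-fold (log2 1.37, SE 0.24, adjusted p = 0.0164), Nbl1, a BMP antagonist, 2.43-fold (log2 1.28, SE 0.16) and Mgp, an inhibitor of mineralisation, 2.13-fold (log2 1.09, SE 0.15). Ets2 (log2 1.02, SE 0.13), Aopep (0.89, SE 0.14), Dlx5 (0.86, SE 0.17) and Dhrs3 (0.85, SE 0.14) rose as well, Ets2 on 2 of 5 clones and Aopep and Dhrs3 on 1 of 4 each. Lef1 rose 1.75-fold (log2 0.81, SE 0.16, adjusted p = 0.0425), and Tcf7, its relative, by 0.63 on the log2 scale (SE 0.12, adjusted p = 0.0462; chosen after its values were seen). Other clones of Nbl1 (0.19), Lef1 (0.50), Ets2 (from -0.06) and Dhrs3 (from 0.07) were not called.

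Other genes fell at 4 h. Wwp2, an E3 ubiquitin ligase, fell by 0.99 on the log2 scale (SE 0.19, adjusted p = 0.0323), and Amot, the junction protein angiomotin, fell by 0.95 (SE 0.14, adjusted p = 0.00369). Krt18, a simple epithelial keratin, fell by 0.92 (SE 0.14). Mterf4 fell by 0.93 (SE 0.11) and Tnfrsf9 fell by 0.72 (SE 0.10). Other clones of Krt18 (up to 0.12) and Mterf4 (up to 0.04) were not called.

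Ccnd1 was called on 1 of 5 clones at 4 h (log2 0.72, SE 0.14, adjusted p = 0.0351); its brightest clone had 0.52 (SE 0.14, adjusted p = 0.201; 0.034 with the labelling batch as a block; 0.0239 to 0.766 over its alternatives). The bright clone of Mycn had 0.26 (SE 0.21, adjusted p = 0.919), the dimmer Mycn clone had 1.31 (adjusted p = 0.0835) and the unnamed clone described as N-myc was called at 1.95 (adjusted p = 1.1e-06). The dimmer Mycn clone was called without Wnt3a 4 h replicate 2 (adjusted p = 0.0123; 0.000216 to 0.254 over its alternatives). Col2a1 had -0.35 (SE 0.49) and -0.52 on its clones.

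In limma, for Wnt3a against vehicle at 4 h, 63 of 27243 clones were called (1960 at an unadjusted p under 0.05), 50 higher and 13 lower, for 27 named genes higher, 7 lower and 21 unnamed clones. The split of higher to lower depended on the processing: it was 133 to 114 with plain background subtraction, 157 to 127 with the deposited values and 82 to 45 when the arrays were scaled to equal spread. With the labelling batch as a block 339 were higher and 133 lower, all 63 among them. Within the 25 pmol and the 30 pmol batch, with 2 against 2 arrays each, limma called 0 clones, with 2839 and 4392 at an unadjusted p under 0.05. The 63 clones had the same direction in both batches, which follows from their Wnt3a and vehicle arrays not overlapping and is no separate support. The count fell to 38 without vehicle replicate 3, 36 without vehicle replicate 4, and 34, 33 and 38 without Wnt3a replicates 1, 3 and 4.

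Apcdd1, Tnfrsf19, Nkd2, Nbl1, Mgp, Ets2, Aopep, Dhrs3, Amot, Mterf4, Krt18 and Tnfrsf9 were called at 4 h without any single array. Lef1 and Dlx5 lost their calls without any of the vehicle replicates or Wnt3a replicates 1, 3 or 4 (adjusted p up to 0.166 and 0.14), and the called clone of Ccnd1 without any of the 8 arrays (up to 0.144). Rprm lost its call without vehicle replicates 3 or 4 or Wnt3a replicates 1, 3 or 4 (up to 0.0678), and Wwp2 without vehicle replicates 2, 3 or 4 or Wnt3a replicates 1, 3 or 4 (up to 0.135). A fit of the 4 h groups alone ended the calls of Lef1, Rprm, Dlx5, Ccnd1, Wwp2, Tnfrsf9, Amot, Nbl1, Aopep and Dhrs3. Scaling the arrays to equal spread ended those of Nkd2 (adjusted p = 0.138; 1.08e-07 to 0.138 over its alternatives) and Ets2 (0.129; 0.000257 to 0.129).

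Myc target and ribosome biogenesis genes rose at 4 h: 37 of 40 were positive, with a median of 0.38 (camera adjusted p = 3.95e-16; 0.000927 with an estimated correlation). Over all genes 2 were called, the nucleolar ribosome biogenesis genes Ppan (log2 0.65, SE 0.12, adjusted p = 0.0314) and Nop56 (0.74, SE 0.15, adjusted p = 0.0477; its other clone 0.15), and 19 when adjusted over the list alone. Ppan lost its call without vehicle replicates 1, 2 or 4 or Wnt3a replicates 1, 3 or 4 (adjusted p up to 0.135), and Nop56 without vehicle replicates 2, 3 or 4 or any Wnt3a replicate (up to 0.196), and both lost it in a fit of the 4 h groups alone. Wnt feedback and target genes rose (13 of 19 positive, median 0.25, adjusted p = 1.62e-07; 0.000927 with an estimated correlation), with 5 called over all genes (Apcdd1, Tnfrsf19, Nkd2, Lef1 and Tcf7) and 8 adjusted over the list alone. G2/M genes fell: 26 of 37 were negative, with a median of -0.11 (adjusted p = 0.00114; 0.00921 with an estimated correlation). No G2/M gene was called over all genes or adjusted over the list alone; Nek2, a mitotic kinase, had -0.56 (SE 0.18) and Anln -0.36 (SE 0.12). Chondrogenic genes fell (9 negative and 4 positive of 14 measured, median -0.16, adjusted p = 0.00856), a call lost at adjusted p = 0.0683 with an estimated correlation. The chondrogenic call was also lost without vehicle 4 h replicate 1 (0.0664) or Wnt3a 4 h replicate 2 (0.0908); Wwp2 was its only member called, over all genes and adjusted over the list alone. In total 4 lists passed at 4 h, 3 with an estimated correlation, 4 with fry and 4 with the labelling batch as a block. With every measured member in the test 6 passed, as BMP/TGF-beta response genes (median -0.12) and actin cytoskeleton genes (median -0.18) were called lower too, both at adjusted p = 0.0467.

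**Figure D3:**
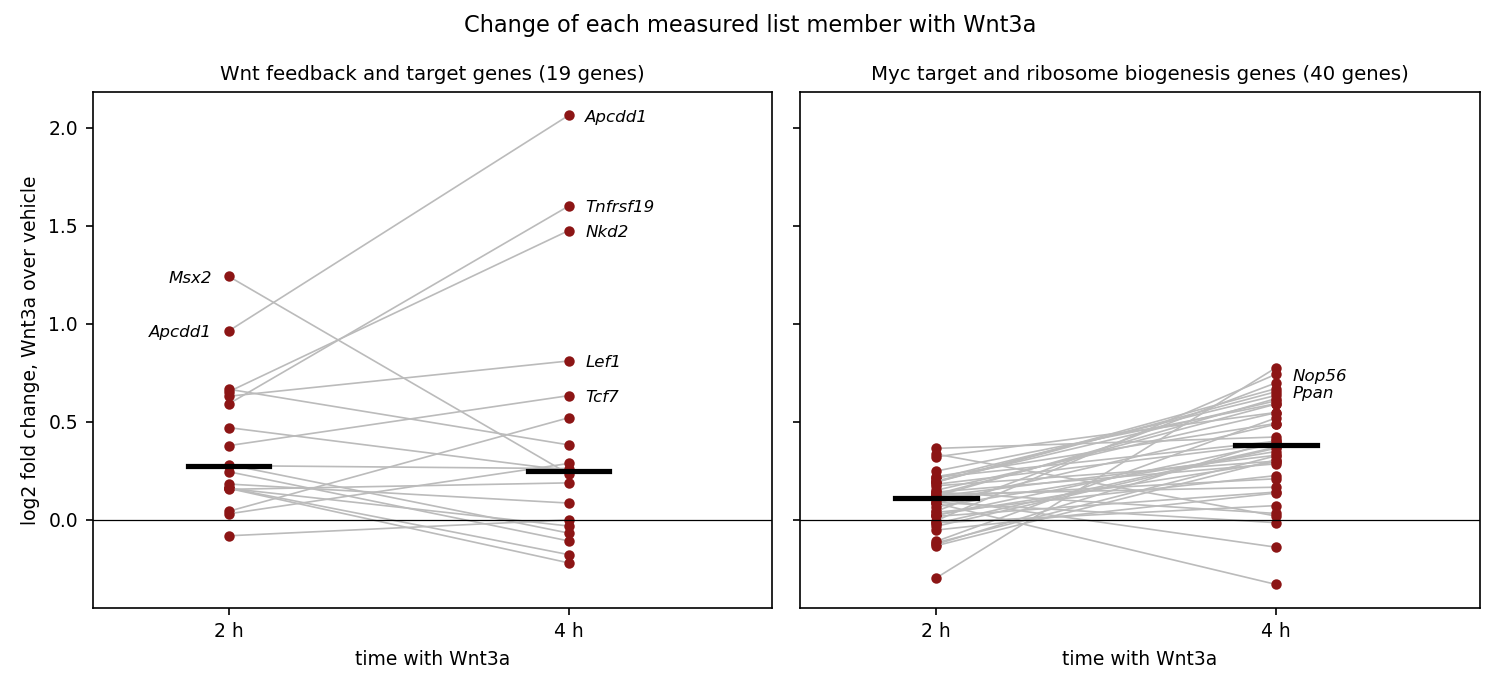
Log2 fold change of Wnt3a over vehicle (y axis) at 2 h and 4 h (x axis) for each of 19 Wnt feedback and target genes and 40 Myc target and ribosome biogenesis genes, 1 joined line per gene, with a black bar at the median and called genes named. The median of the Wnt list was 0.28 at 2 h and 0.25 at 4 h, and that of the Myc list 0.11 and 0.38.

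Clones called higher at both times numbered 5, where 0.0275 would be shared by independent sets of these sizes (Fisher's exact test, p = 5.02e-11, 15 and 50 clones of 27243). These were the clones of Apcdd1 and Dlx5, Ets2 2200002C21 and 2 unnamed clones, that described as N-myc and one of unknown identity; Dhrs3 was called on a different clone at each time. Of the 50 clones higher at 4 h, 42 were positive at 2 h, and of the 15 higher at 2 h, 11 were positive at 4 h. Of the 13 lower at 4 h, 7 were negative at 2 h. With the labelling batch as a block 13 clones were called higher at both times (0.548 with independent sets). Both comparisons took the residual spread of a clone from the same fit, which favours calls of a low-spread clone at both times. Clones are also not independent of each other. The numbers expected with independent sets and the Fisher p-value therefore do not measure a shared response alone.

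The difference between the Wnt3a effects at 4 h and 2 h asked whether the answer changes with time. No single gene was called. Apcdd1 had a larger effect at 4 h by 1.10 on the log2 scale (SE 0.19, adjusted p = 0.174) and Tnfrsf19 by 1.01 (SE 0.27, adjusted p = 0.673). Msx2 had -1.01 (SE 0.31), Tbx18 -1.06 (SE 0.28), Fgfrl1 -0.82 (SE 0.23) and Fgf10 -0.72 (SE 0.24). The Msx2 value turned to 0.85 when the arrays were scaled to equal spread. In limma 0 of 27243 clones were called and 1458 had an unadjusted p under 0.05. With the labelling batch as a block 11 were called (4 higher, 7 lower). Leaving out vehicle 4 h replicate 1 gave 2 calls, and leaving out vehicle 4 h replicate 2 gave 1.

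Between lists the difference passed for 10. Myc target and ribosome biogenesis genes had the larger effect at 4 h (35 of 40 positive, median 0.28, adjusted p = 5.05e-06; 0.034 with an estimated correlation), with Nop56 at 0.75 (SE 0.21) and Ppan at 0.46. The effect was lower at 4 h than at 2 h for limb patterning genes (20 of 26 negative, median -0.22, adjusted p = 0.000987; 0.0281 with an estimated correlation), though their median turned to 0.09 with plain background subtraction and to 0.11 with the deposited values. It was lower for G2/M genes (28 of 37 negative, median -0.17, adjusted p = 0.00157; 0.0281 with an estimated correlation), with Pttg1 at -0.45 and Kif23 at -0.50, which turned to 0.24 and 0.21 when the arrays were scaled to equal spread. Actin cytoskeleton genes (15 of 19 negative, median -0.16, adjusted p = 0.00873; 0.0473 with an estimated correlation) held Cnn2 at -0.91 and Des at -0.56. BMP/TGF-beta response genes (12 of 15 negative, median -0.15, adjusted p = 0.0124; 0.0473 with an estimated correlation) held Smad6 at -0.59 and Tgfbi at -0.38, the latter not well above background at 4 h.

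The other lists with a lower effect at 4 h lost their calls with an estimated correlation. They were FGF/ERK response genes (median -0.13, adjusted p = 0.00726; adjusted p = 0.0612 with an estimated correlation), chondrogenic genes (-0.22, 0.0258; adjusted p = 0.0849 with an estimated correlation), soft connective tissue genes (-0.12, 0.0323; adjusted p = 0.0672 with an estimated correlation; median 0.0082 with plain background subtraction), erythroid genes (-0.45, 0.0323; adjusted p = 0.191 with an estimated correlation) and inflammatory and interferon genes (-0.12, 0.0339; adjusted p = 0.263 with an estimated correlation). Members with the smallest p were Col9a1 (-0.44) of the chondrogenic list, Col5a1 (-0.59) and Fbn2 (-0.77; 0.30 when scaled to equal spread) of the soft connective tissue list, Hbb-y (-1.41) and Hbb-bh1 (-0.72) of the erythroid list, and Vcam1 (-0.58) and Ccl7 (-0.49) of the inflammatory list. Adjusted over the list alone, 2 FGF/ERK, 2 erythroid, 1 limb patterning, 1 chondrogenic and 1 soft connective tissue gene were lower. Wnt feedback and target genes had a negative median (-0.01), a positive mean (0.05) and an upward test (adjusted p = 0.784), with 3 higher and 1 lower adjusted over the list alone. Against 10 lists past the preset test, 5 passed with an estimated correlation, 2 with fry and 9 with the labelling batch as a block, where the erythroid call was lost (0.0748). With the replicate block the inflammatory call was lost (0.0916). With every measured member in the test the same 10 lists passed.

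Without Wnt3a 2 h replicate 3, 4 lists of the difference passed, and without Wnt3a 4 h replicate 2, 5 did. The FGF/ERK call was lost without Wnt3a 4 h replicate 2 (adjusted p = 0.0944), the cytoskeleton call without Wnt3a 2 h replicate 3 (0.0629), and the BMP/TGF-beta call without either of these arrays (up to 0.0933). The chondrogenic call was lost without vehicle 2 h replicate 1, Wnt3a 2 h replicate 3, vehicle 4 h replicate 1 or Wnt3a 4 h replicate 2 (up to 0.0944). The soft connective tissue call was lost without vehicle 2 h replicate 3, Wnt3a 2 h replicates 2 or 3, vehicle 4 h replicate 2 or Wnt3a 4 h replicate 2 (up to 0.161). The erythroid call was lost without vehicle 2 h replicates 1, 2 or 4, Wnt3a 2 h replicates 3 or 4, vehicle 4 h replicate 1 or Wnt3a 4 h replicates 3 or 4 (up to 0.107). The inflammatory call was lost without vehicle 2 h replicates 4 or 5, Wnt3a 2 h replicates 1 or 3, vehicle 4 h replicate 2 or Wnt3a 4 h replicates 1, 2 or 3 (up to 0.312).

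**Figure D4:**
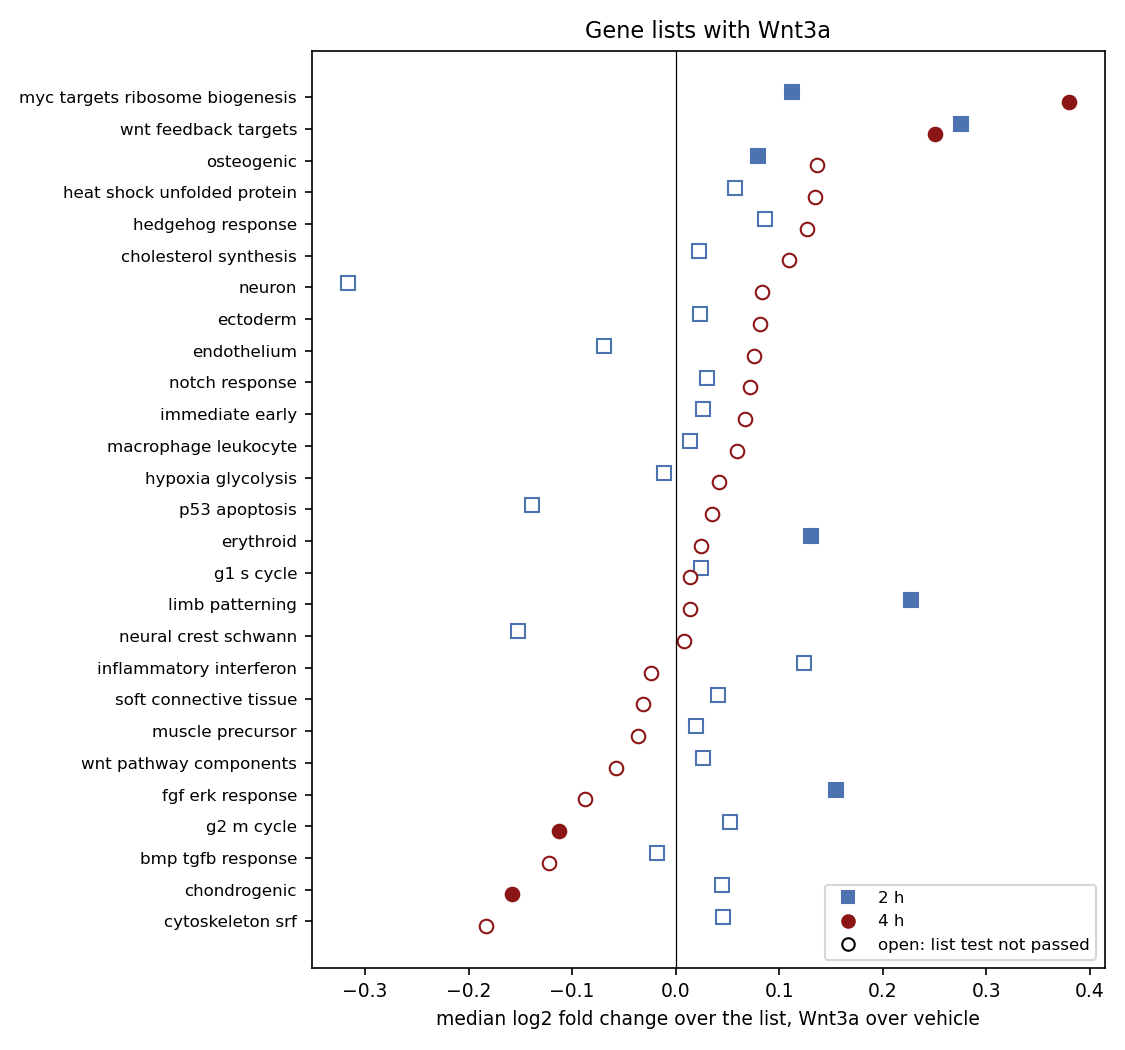
Median log2 fold change of Wnt3a over vehicle (x axis) over each of 27 gene lists (y axis, ordered by the 4 h value), with squares for 2 h, circles for 4 h and open symbols where the list test was not passed. The Myc list stands highest at 4 h (0.38) and the chondrogenic list had -0.16.

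The vehicle groups at 4 h and 2 h were compared to show how the cultures differ between times without Wnt3a. Labelling batch and a stronger shrinkage of ratios on the dimmer 4 h arrays are not separated from time in these values. Globin genes were higher at 4 h: Hba-x by 2.57 on the log2 scale (SE 0.27, adjusted p = 3.69e-06), Hbb-bh1 by 1.91 (SE 0.16), Hbb-y by 2.07 and Hba-a1 by 1.44, the last turning to -0.14 when the arrays were scaled to equal spread. Hedgehog response genes were lower, with Gli3, a transcription factor of the pathway, at -1.60 (SE 0.15; not well above background at 4 h), Cdon at -0.97 (SE 0.15), Gas1 at -0.87 (SE 0.18) and Gli2 at -0.70 (SE 0.14). The lowest called genes were Rbm8a (-3.76, SE 0.37; its other clone 0.13), Cdkn3 (-3.67, SE 0.32), Stra6, a retinol-binding protein receptor (-3.34, SE 0.31), Kdm2a (-3.25, SE 0.39; other clones up to 0.31) and Sec14l1 (-3.22, SE 0.20; its other clone -0.42). The highest were Gpm6a (3.71, SE 0.45), Ndrg4 (3.51, SE 0.33), Mt1 (3.46, SE 0.42; other clones down to -0.17), Golga3 (3.38, SE 0.19) and Afp (3.17, SE 0.74). Gpm6a, Ndrg4, Mt1 and Golga3 were not well above background on any vehicle array at 4 h, so these values do not measure the size of a rise; Ndrg4 had 0.52 (adjusted p = 0.412, the highest over its alternatives, 9.51e-08 the lowest) with the deposited values. Afp was well above background on 2 of 4 arrays, and its call was lost with the labelling batch as a random block (adjusted p = 0.115; 9.44e-05 to 0.116 over its alternatives).

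In limma, for vehicle at 4 h against vehicle at 2 h, 6034 of 27243 clones (22.1%) differed, 3006 higher and 3028 lower, for 1588 and 1654 named genes. With the deposited values 657 were higher and 3377 lower, where the median of all clones shifted by -0.21. Time and labelling batch could not be separated here: no probe amount occurs at both times, 2528 clones were called with the batch as a random block, and within the 2 h arrays 11007 of 27054 clones (40.7%) differed between batches. Erythroid genes were higher (11 of 11 positive, median 0.86, adjusted p = 1.24e-05; 0.0362 with an estimated correlation; 6 called over all genes, 7 adjusted over the list alone). Hedgehog response genes (median -0.70, adjusted p = 0.00445; 0.0362 with an estimated correlation; 4 called over all genes and 4 adjusted over the list alone) and soft connective tissue genes (-0.33, 0.0135; 0.046 with an estimated correlation; 10 lower and 1 higher over all genes, 12 and 1 adjusted over the list alone) were lower. In the latter, Lum had -1.03 (SE 0.18) and Col3a1 -0.79, with another Col3a1 clone at 1.27, while Postn had 0.90 with another clone at -0.61.

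Osteogenic, Wnt target and limb patterning lists were lower in the vehicle comparison but lost their calls with an estimated correlation. Osteogenic genes (median -0.51, adjusted p = 0.0173; adjusted p = 0.0839 with an estimated correlation; 4 lower over all genes and 4 adjusted over the list alone) included Twist1 at -0.83, Spp1 at -0.68, Dlx5 at -0.55 and Alpl at -0.47. Spp1 turned to 0.38 with plain background subtraction. Wnt feedback and target genes (-0.39, 0.0266; adjusted p = 0.0839 with an estimated correlation; 6 lower and 2 higher over all genes, 9 and 2 adjusted over the list alone) included Wif1 at -0.97 (not well above background at 4 h), Ccnd1 at -0.79, Sall4 at -0.84 and Cd44 at 0.41, whose mean over clones was -0.43. Limb patterning genes (-0.26, 0.0351; adjusted p = 0.105 with an estimated correlation; 4 lower and 2 higher over all genes and adjusted over the list alone) included Tbx18 at -0.80, Prrx1 at -0.73 and Emx2 at -0.45. In total 6 lists passed, 3 with an estimated correlation, 18 with fry and 0 with the labelling batch as a random block. With every measured member in the test 8 passed: the limb patterning call was lost (0.0617), and inflammatory and interferon (0.0162), actin cytoskeleton (0.0423) and endothelium genes (0.0423) were called lower.

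Without vehicle 4 h replicate 2, 3 lists of the vehicle comparison passed. The Wnt target (adjusted p = 0.0504) and osteogenic (0.0501) calls were then lost, and the limb patterning call was lost without that array, vehicle 2 h replicate 1 or vehicle 4 h replicate 1 (up to 0.0684). Twist1 lost its call without vehicle 4 h replicate 1 (0.0525), Alpl without vehicle 4 h replicate 3 (0.0774), Dlx5 without vehicle 2 h replicate 1 or vehicle 4 h replicate 4 (up to 0.0783) and Emx2 without vehicle 2 h replicate 1 or vehicle 4 h replicates 3 or 4 (up to 0.0723).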

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

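All tests below were chosen after the result they bear on was seen, except the test of bright clones far below the reference and the test by clone brightness.

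Values of single arrays far from the others of their group were looked for in 111 groups of arrays and found in 5, and chance gives about 1 in 20. Col2a1 on vehicle 2 h replicate 1 was at -0.68 (others 0.82 to 1.32). Hbb-y H3118A04 on the same array was at -5.41 (others -4.93 to -4.77). Msx2 on vehicle 2 h replicate 5 was at 3.12 (others 2.35 to 2.57). The dimmer Mycn clone on vehicle 2 h replicate 5 was at 2.12 (others 0.80 to 0.90). Ddx18 on Wnt3a 2 h replicate 4 was at 1.83 (others 1.47 to 1.53).

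Lists whose Wnt3a effect differed between 4 h and 2 h by the list test had these median log2 differences: Myc target and ribosome biogenesis genes 0.28, limb patterning -0.22, chondrogenic -0.22, G2/M -0.17, BMP/TGF-beta response -0.15 and actin cytoskeleton genes -0.16. For FGF/ERK response genes it was -0.13, for soft connective tissue -0.12, for inflammatory and interferon genes -0.12 and for erythroid genes -0.45. The background offset may shrink ratios more on the dimmer 4 h arrays. If alike in both 4 h groups, this would move Wnt3a effects towards 0. For 2 lists called lower at 4 h the medians argue against it as the only source. They were 0.05 at 2 h and -0.11 at 4 h for G2/M genes, and 0.04 and -0.16 for chondrogenic genes. The other negative differences are not separated from such a shrinkage.

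The clones of Hba-a1, Hba-x, Hbb-y and Hbb-bh1 were higher with Wnt3a at 2 h (median 0.87 over 31 clones) and not at 4 h (median 0.02). A distortion of bright spots far below the reference is argued against by the 377 other such clones, whose median change was -0.12 (quartiles -0.24 and -0.03). The labelling batch alone is argued against by the median of 0.73 within the 40 pmol arrays. More blood cells or blood cell RNA in the Wnt3a cultures remains possible and cannot be told apart from a change of globin RNA, since no value decides. The lowest mean of the 4 genes, that of Hbb-bh1, was 0.26, and Hbb-b1, left out of the 4, had 0.02. Other genes of the red blood cell list had lower values: Slc4a1 had -0.05 (95% interval -0.79 to 0.69), Car2 -0.48 (-1.11 to 0.15), Alas2 -0.38 (-0.93 to 0.17), Gata1 0.13, Hebp1 0.08 and Epb42 0.05. These values go against blood cells without excluding them, because Car2 and Alas2 were at 1.81 and 1.58 times background with vehicle, and the log2 ratios to the reference of Gata1 and Epb42 were 1.3 and -0.64, where RNA of other cells can hide a rise. Slc4a1 has a wide interval. Hebp1, at 15.6 times background (interval -0.21 to 0.37), is a single gene whose level in the other cells of the culture was not measured. A direct effect of Wnt3a on globin genes was not tested.

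Clones listed as Mycn differed in their response. Saturation of the scanner at the bright clone is argued against by a highest share of saturated Cy5 pixels at that spot of 0%. Vehicle 2 h replicate 5 as a mislabelled Wnt3a culture is argued against by its log2 ratio of 1.09 for the unnamed clone described as N-myc, where the lowest Wnt3a 2 h array had 2.83. Whether the bright clone reports another transcript stays open. The upper 95% bound of its change was 0.70 at 2 h, where the lower bound of the dimmer Mycn clone was 0.82, and 0.705 at 4 h, where that lower bound was 0.7049, so these bounds parted at 2 h and met at 4 h. Such bounds restate that the clones differ and do not test why, and clone sequences were not used here.

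A large share of clones differed between the vehicle groups at 4 h and 2 h. The labelling batch or day cannot be told apart from time, since no batch holds both times and 40.7% of clones differed between batches within 2 h (2.01% within 4 h). The lower signal over background on the 4 h arrays also stays open. The share called was 20.9% of the brightest 9081 clones, 23.5% of the 9081 in the middle and 22.1% of the dimmest 9081, so dim clones alone could not account for it. These shares do not test whether ratios far from the reference were shrunk more on the 4 h arrays. Each list past the test in the main fit moved towards the reference. Erythroid genes (median log2 ratio with vehicle -2.50) were higher, and hedgehog (1.00), limb patterning (0.84) and soft connective tissue genes (0.65) were lower. Endothelium genes (-0.44), called lower only with every measured member in the test, went the other way. Some lists above the reference that did not pass changed little. G2/M genes (0.81) changed by a median of 0.03, BMP/TGF-beta response genes (0.90) by -0.06 and Myc target genes (0.66) by -0.02. Others that did not pass moved towards the reference, such as actin cytoskeleton genes (1.34) by -0.21 and neuron genes (-2.83) by 0.29. A change of the cells during culture, which the design includes, was not tested apart from the labelling batch and the lower signal.

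Other splits of the arrays into groups of the same sizes were fitted in the same way. The replicate numbers were taken to pair the 2 h arrays, though only number 1 correlated best with its own. If they are pairs, 16 splits part all of them as the real one does, which are too few for a share under 0.05. Among these 16, the real split gave 15 clones called at 2 h and the highest other 1; with the labelling batch as a block it gave 47 and the highest other 9. Splits that part fewer pairs differ in that same-numbered arrays fall into 1 group, so they do not decide if the numbers are pairs. With them, 1 of 100 splits gave as many clones (highest other 10), and 1 of 70 with the labelling batch as a block (highest other 9). For clones called at 4 h, 2 of 35 splits gave as many (63; highest other 737), so chance cannot be excluded by that count. The other split parts the 25 pmol from the 30 pmol arrays and points to a structure of the samples by labelling batch. With that batch as a block 472 clones were called at 4 h, the highest other split gave 18, and 1 of 18 splits gave as many, which are too few splits for a share under 0.05. For the difference between times the real count was 0, so 100 of 100 splits gave as many by construction. That count of splits decides nothing. Times were reassigned within each treatment there, which can carry the difference between 2 h and 4 h arrays into this contrast. The highest other, 5434, therefore measures no level of chance. For the vehicle comparison 1 of 100 splits gave as many (6034, highest other 2710). The highest other set vehicle 2 h replicates 1 to 4 against the remaining arrays. That is nearly the real grouping in reverse and does not show what an unrelated grouping gives. The splits also ignore the labelling batches, each of which lies within 1 time, so they do not decide. For the number of lists past the test chance was not excluded in any comparison, but these counts could hardly exclude it. Splits near the real grouping or near its reverse keep much of its difference. At 2 h, 5 of 100 splits gave as many (6, highest other 9), as did 3 of the 16 that part all pairs (highest other 9). The others among these differed from the real grouping or its reverse by at most 1 array per group. As many lists passed in 3 of 35 splits at 4 h (4, highest other 5) and 9 of 100 for the vehicle groups (6, highest other 9). They passed in 7 of 100 for the difference (10, highest other 11), where the splits can carry in the difference between times.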

How the results depend on the processing

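The mean foreground signal, the random batch block for the Wnt3a comparisons, the batch block in the list test, the list test with every measured member and the model without both 27 pmol arrays were chosen after seeing the data, as were the looser use of spot flags and leaving out clones marked as failed, which moved no count by over 1.5 times. Signal over background of 1.41 to 1.91 on the 4 h arrays limits what can be said of dim clones. Over all settings, the 62 results for called genes kept direction and call in 1420 of 1641 cases, lost the call in 218 and turned in 3. The 38 results for uncalled genes stayed uncalled in 1137 of 1185 cases, were called in 35 and turned in 13. The 26 list results kept their call in 577 of 678 cases and lost it in 101.

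For Wnt3a against vehicle at 2 h (15 clones called), other settings gave 23 with no background subtraction, 9 with median centring, 0 with scale normalization, 26 with the deposited values, 26 with the mean foreground, 3 with a trend and robust prior and 180 with array weights (134 higher, 46 lower). They gave 47 with the labelling batch as a fixed block, 40 as a random block and 9 with both 27 pmol arrays left out of the model of all groups. For Wnt3a against vehicle at 4 h (63), they gave 247 with plain subtraction, 32 with median centring, 127 with scale normalization, 284 with the deposited values, 127 with array weights, 103 at an adjusted p under 0.10, 16 with the 4 h groups alone, 472 and 340 with the batch as a fixed or random block and 39 with the mean over clones. The split of 50 to 13 became 133 to 114 with plain subtraction, 82 to 45 with scale normalization and 157 to 127 with the deposited values. For the Wnt3a effect at 4 h minus Wnt3a effect at 2 h (0), they gave 1 with plain subtraction, 2 with print-tip loess, 1 with scale normalization, 7 with the deposited values, 8 with array weights, 11 and 10 with the batch as a fixed or random block and 5 with the mean over clones. For vehicle at 4 h against vehicle at 2 h (6034), they gave 3897 with scale normalization, 2528 with the random block and 2227 with the mean over clones, where fewer items were tested. With the deposited values the median of all clones shifted by -0.21 in that comparison, and 657 were higher and 3377 lower, read relative to that shift. Without 1 array the counts were 4 to 23 at 2 h, 33 to 63 at 4 h, 0 to 2 for the difference and 4600 to 5470 for the vehicle groups. The cause was not tested.

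For lists, the 10 of the difference became 6 with no background subtraction, 3 with plain subtraction, 4 with the deposited values, 5 with an estimated correlation and 2 with fry. The 4 at 4 h became 2 and the 6 of the vehicle comparison 3 with plain subtraction, and the latter 3 with an estimated correlation and 18 with fry. The 6 at 2 h became 10 without both 27 pmol arrays. Without 1 array the lists numbered 5 to 8 at 2 h, 3 to 6 at 4 h, 4 to 10 for the difference and 3 to 8 for the vehicle groups. The cause was not tested.

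Values that turned sign were these. The brightest Ccnd1 clone at 2 h (0.04) had -0.0080 with plain subtraction, -0.17 with scale normalization, -0.045 with the deposited values and -0.025 to 0.15 without 1 array. Scale normalization also turned the other named Ccnd1 clone at 2 h (-0.026), the differences of Msx2 (0.85), Fbn2 (0.30), Pttg1 (0.24) and Kif23 (0.21), and Hba-a1 in the vehicle comparison (-0.14). Col2a1 at 2 h (-0.14) had 0.17 with array weights, 0.11 without both 27 pmol arrays and -0.48 to 0.45 without 1 array. Spp1 in the vehicle comparison had 0.38 with plain subtraction, and Cd44 there had -0.43 as the mean over clones. The cause was not tested.

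With the replicate number as a block, 24 clones were called for Wnt3a against vehicle at 2 h, 130 for Wnt3a against vehicle at 4 h (91 higher, 39 lower), 0 for the difference and 6024 for vehicle at 4 h against vehicle at 2 h. At 2 h, where the numbers were taken to pair the arrays, the block changed no named call or list call other than those given beside the results. At 4 h the numbers were not taken to pair the arrays. Deviations correlated there between arrays of the same number at 0.175, 0.0072, 0.028 and 0.184, not all above 0.1, and 2 of 4 numbers correlated best with their own. There the block ended the call of Dlx5 (adjusted p = 0.05; 0.00144 to 0.528 over its alternatives) and gave one for the dimmer Mycn clone (0.0301; 0.000216 to 0.254).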

Other observations

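All values of genes named here outside the rule for named genes were chosen after they were seen, and so was the test of the 4 h clones on the 2 h arrays. At 4 h with Wnt3a, Cxcl12, a chemokine of mesenchyme, was called higher on 3 clones (log2 0.70, 0.71 and 0.99), and Sdc2, a cell surface proteoglycan, on 3 clones (0.72, 0.76 and 0.49). Fasn, a fatty acid synthase, was called at 0.65, and Nip7, a ribosome biogenesis factor, at 0.70. Hsph1, a heat shock protein, had 0.83 (adjusted p = 0.0576; 0.0158 with the labelling batch as a block), Gadd45b -0.75 (0.209; 0.00592 with the block), Dsp, a desmosome protein, 0.57 (0.212; 0.031) and Aen 0.55 (0.564; 0.00685).

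The remaining 14 lists passed camera at the preset correlation in no comparison of the main fit. In the vehicle comparison endothelium passed when every measured member was tested. Fry passed 18 of 27 lists there, so some of these 14 were among them. At 2 h and 4 h the median log2 fold changes with Wnt3a were 0.03 and -0.06 for Wnt pathway components (22 genes; adjusted p = 0.612 and 0.356), with Gsk3b at -0.35 at 4 h, and 0.03 and 0.07 for Notch response genes (11; 0.997 for 2 h and 0.972 for 4 h), whose means were 0.01 and 0.01 and whose 4 h test pointed down. They were 0.02 and 0.01 for G1/S genes (36; 0.722 and 0.691; 4 h mean -0.01), 0.03 and 0.07 for immediate early genes (22; 0.797 and 0.995; 4 h mean -0.03), 0.06 and 0.13 for heat shock and unfolded protein genes (18; 0.492 and 0.523) and -0.01 and 0.04 for hypoxia and glycolysis genes (23; 0.897 and 0.939). They were -0.14 and 0.03 for p53 and apoptosis genes (11; 0.257 and 0.972) and 0.02 and 0.11 for cholesterol synthesis genes (15; 0.997 and 0.185), with Sqle at 0.52 at 4 h. Adjusted over the list alone, 1 heat shock gene was called higher at 4 h, and 1 immediate early gene higher and 2 lower.

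Cell type lists at 2 h and 4 h had medians of 0.02 and -0.04 for muscle precursors (14; adjusted p = 0.931 and 0.552; 2 h mean 0.04, with a downward test), 0.02 and 0.08 for ectoderm (15; 0.774 and 0.635; 2 h mean -0.0080, with a downward test; 1 higher adjusted over the list alone at 4 h) and -0.07 and 0.08 for endothelium (16; 0.42 and 0.972). They were 0.01 and 0.06 for macrophages and leukocytes (14; 0.612 and 0.939; 2 h mean -0.05, with Mrc1 lower adjusted over the list alone at 2 h), -0.15 and 0.0084 for neural crest and Schwann cells (5; 0.0878 and 0.897) and -0.32 and 0.08 for neurons (10; 0.0795 and 0.995; the 4 h mean of 0.09 and its downward test differ in sign). On the clones used for the lists, the main fit called no member of these 14 lists over all genes at either time. The called clone of Krt18, an ectoderm gene, was not the clone of highest signal. With the labelling batch as a block, members called at 4 h included Egr1 (log2 0.54, limma adjusted p = 0.0186), Hsph1, Gadd45b, Dsp and Aen.

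Lists that passed in other comparisons had these medians where they did not pass with Wnt3a. Soft connective tissue genes had 0.04 at 2 h and -0.03 at 4 h (25 genes; adjusted p = 0.0536 and 0.552), with 2 higher at 2 h adjusted over the list alone (Twist1, Twist2) and 3 higher and 3 lower at 4 h. Hedgehog response genes had 0.09 and 0.13 (7; 0.257 and 0.995; Gli3 higher at 2 h and 1 gene, Boc, lower at 4 h adjusted over the list alone). BMP/TGF-beta response genes had -0.02 and -0.12 (15; 0.42 and 0.0502; 2 h mean 0.06; Bmp4 higher at 2 h adjusted over the list alone). Inflammatory and interferon genes had 0.12 and -0.02 (18; 0.0779 and 0.487), and actin cytoskeleton genes 0.05 and -0.18 (19; 0.151 and 0.0761). At 2 h G2/M genes had 0.05 (0.612) and chondrogenic genes 0.04 (0.967; mean -0.02, with a downward test). At 4 h FGF/ERK response genes had -0.09 (0.329), erythroid genes 0.02 (0.897; mean -0.0060, with an upward test), osteogenic genes 0.14 (0.487; 2 higher and 1 lower adjusted over the list alone) and limb patterning genes 0.01 (0.972), whose mean of -0.02 and downward test differ in sign from the median.

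A hypothesis is that the response called at 4 h was partly under way at 2 h. The 63 clones called at 4 h were scored on the 2 h arrays as their mean log2 ratio signed by the 4 h direction. Wnt3a arrays lay 0.32 above vehicle arrays, with the lowest Wnt3a array at 0.17 and the highest vehicle array at -0.07 (exact two-sided permutation p = 0.0625 over the 16 exchanges within replicate numbers, the smallest they can give). If the numbers are pairs, they are therefore too few for a p under 0.05, and this test does not decide for the 63 clones as a set. Without pairs, the exact permutation p was 0.00794 over 126 splits, the smallest they can give. Among single clones, 5 were called higher at both times, so for these a rise was already called at 2 h. In the 27 pmol pair the vehicle array was at -0.12 and the Wnt3a array at 0.17.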
